A study of Mus musculus with 9 samples.

How the data were processed

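RNA from mouse lung was sequenced in 9 samples of 3 groups with 3 samples each. The groups, taken from the treatment given in the labels, are normoxia, hypoxia, and hypoxia with a knockdown of Hif1a, the gene of the oxygen-regulated transcription factor subunit HIF-1α. The sample titles carry the word muscle, whereas the source and tissue fields give lung, so marker genes of both tissues were tabulated as a check. The labels do not give the oxygen level, the length of exposure, the way the knockdown was made, the time of tissue collection or whether each sample came from its own animal. The p-values therefore measure the spread between these samples, part of which may be technical.

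The deposited table holds whole-number read counts per gene, not normalised, for all 9 samples. Per the labels' protocols, RNA was isolated with the RNeasy Mini Plus kit and libraries were made from total RNA with the NEBNext Ultra RNA kit. Per the submitters' processing notes, bcl2fastq, HISAT2, TopHat, StringTie, limma and DESeq were used with genome build mm10. Their versions and the order of the steps are not given in the sources used here, and neither is the program that made the counts or whether reads were assigned by strand. Of 30400 gene identifiers shared with the GENCODE M21 annotation of GRCm38 (mm10), 651 had the same position in the deposited table, so its positions come from another annotation or build, which it does not name. Positions printed below were taken from GENCODE M21 by gene identifier. Counts of near-identical genes, such as the globin pairs, Hspa1a and Hspa1b, the guanylate-binding proteins and immunoglobulin segments, can be split or shared by the counting step and are uncertain one by one. Overlapping and antisense genes cannot be told apart without strand.

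The table lists 30865 genes, all with at least 1 count. Symbols were taken from the table itself, where 158 genes had none and 34 symbols stood on more than 1 gene. Library totals ran from 15566485 to 18046442 counts, and between 23336 and 24247 genes had a count in a library. A count of 3 corresponded to 0.166 to 0.193 CPM (counts scaled by library total as in the cpm function of edgeR), which was taken as the floor of detection per library. This floor and the counts behind it cover counting error only, since reads without molecular identifiers are not independent molecules. Replicate pairs of 1 group differed by a chi-square of 12.9 to 25.9 per degree of freedom, so no pair of files held the same library.

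The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 17578, and libraries were scaled by TMM with factors of 0.976 to 1.03. A single quasi-likelihood model over all 9 libraries had 1 coefficient per group, 6 residual degrees of freedom, 4.79 prior degrees of freedom and a common biological coefficient of variation of 17.3%. Hypoxia against normoxia, knockdown against hypoxia and knockdown against normoxia were tested as contrasts with the quasi-likelihood F-test, and a further F-test asked whether a gene differed among the 3 groups. P-values were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. Levels are given as CPM scaled by TMM, as mean ± SD over the 3 libraries of a group. Unless another test is named, each adjusted p comes from this edgeR test.

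Before the data were examined, 45 gene lists covering pathways, RNA quality and cell types of lung and of neighbouring tissues were written down, as were the designs, most of the alternatives and the rule for named genes. Of 988 list entries, 964 matched by symbol, 11 by an older symbol and 13 not at all. The 44 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists of a comparison. The list of replication-dependent histones had too few tested members and gave no test. Camera with a correlation estimated from the data and fry, which asks whether the genes of a list move on balance in 1 direction, served as alternatives. Named genes were Hif1a, Epas1, Vegfa, Slc2a1, Ldha, Pdk1, Ep300, Il1b, Il6, Tnf, Cxcl1 and Ccl2 in each comparison. To these were added the 8 largest rises and the 8 largest falls among changed genes with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted genes, immunoglobulin and T cell receptor segments. Up to 4 members of each list past the threshold completed the rule. Genes named outside it are the tissue markers, the called members Hif1an, Ccl7, Spp1, Bhlhe40 and Adm of lists short of the threshold, the examples of genes called in both comparisons, and genes of the sets chosen after the data had been seen.

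The alternatives were DESeq2 size factors within edgeR, the DESeq2 1.42.0 Wald test (a likelihood ratio test for 3 groups), limma-voom, no low-count filter, at least 1 CPM in 3 libraries, a fit of only the 6 libraries compared, the replicate number as a block, an absolute log2 fold change of at least 1, and leaving out each library in turn. A fit with the cardiac muscle list score as a covariate was added after the data had been seen. In unchanged counts simulated 20 times from the fitted means and dispersions, the hypoxia libraries were shared between both comparisons as in the study. A split of the hypoxia libraries into 1 and 2, each side used for 1 comparison in the model of all 9 libraries, was added after the data had been seen. The test was also run on simulated counts in which 200 genes per altered group had known folds. In the simulated hypoxia against normoxia, over 17309 genes, it recovered 39.1% of genes changed 1.5-fold, 53.9% of those changed 2-fold and 90% of those changed 4-fold, and 6.02% of its calls were false. Confidence intervals of 95% for medians of gene lists came from 10000 bootstrap draws over genes, which are not independent. Correlations between list scores and the figures were made in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.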

Results

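Lung RNA was profiled in 3 normoxia, 3 hypoxia and 3 hypoxia libraries labelled as Hif1a knockdown. The series design asks what sustained hypoxia does to gene expression in mouse lung and what lowering HIF-1α under hypoxia does to it. Totals were 16229815 to 16736131 counts in the normoxia libraries, 17163661 to 17620652 in the hypoxia libraries and 15566485 to 18046442 in those labelled knockdown. The share of mitochondrial counts lay between 1.61% and 2.08%, and the 10 most counted genes took 6.89% to 8.43% of a library. The first principal component held 29.3% of the variance. Its scores were -45.86 to -33.47 in normoxia, -5.10 to 21.2 in hypoxia, where replicate 2 had the lowest score, and 23.91 to 35.23 in the knockdown group. Among the 3 groups, 1397 of 17578 tested genes differed.

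The libraries held lung RNA. Sftpc, which encodes surfactant protein C of alveolar type 2 cells, stood at 13900 ± 1100 CPM in normoxia, 15500 ± 2500 in hypoxia and 16900 ± 2600 in the knockdown group (SD, n = 3). Sftpb (2090 ± 39 CPM in normoxia) and the alveolar type 1 gene Ager (2100 ± 190) were likewise abundant. The skeletal muscle genes Acta1 and Myh4 reached at most 0.27 ± 0.22 and 0.019 ± 0.033 CPM as group means, and Ckm stood at 4.43 ± 3.7 CPM in normoxia. Myh6, the cardiac myosin heavy chain, varied from 1.11 to 441 CPM, with a wide spread inside each group.

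Hif1a, the targeted gene, differed little between the groups. It lies on chromosome 12 at 73901375 to 73947530 of the plus strand in GRCm38 (ENSMUSG00000021109). Its level was 82.3 ± 4.9 CPM in normoxia, 93.4 ± 4.8 in hypoxia and 85.6 ± 0.7 in the libraries labelled knockdown (SD, n = 3). The separate values were 80.3, 87.8 and 78.6 in normoxia, 93.4, 98.3 and 88.6 in hypoxia, and 86.4, 85.5 and 85.0 in the knockdown group. The knockdown libraries lay below each hypoxia library, with a log2 fold change of -0.13 (SE 0.08, adjusted p = 0.62) and a 95% interval of -0.29 to 0.04. A lower Hif1a transcript in the knockdown group was thus not detected, and that group is called by its label below. Epas1, which encodes HIF-2α, was at 1080 ± 150, 879 ± 100 and 751 ± 220 CPM in normoxia, hypoxia and knockdown, with adjusted p of 0.50 for hypoxia and 0.77 for the label. None of the 10 genes of the HIF pathway list passed in either comparison (edgeR, camera adjusted p = 0.64 and 0.62), and Hif1an, an inhibitor of HIF, was the 1 member lower in knockdown than in normoxia (-0.37, adjusted p = 0.013).

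**Figure D1:**
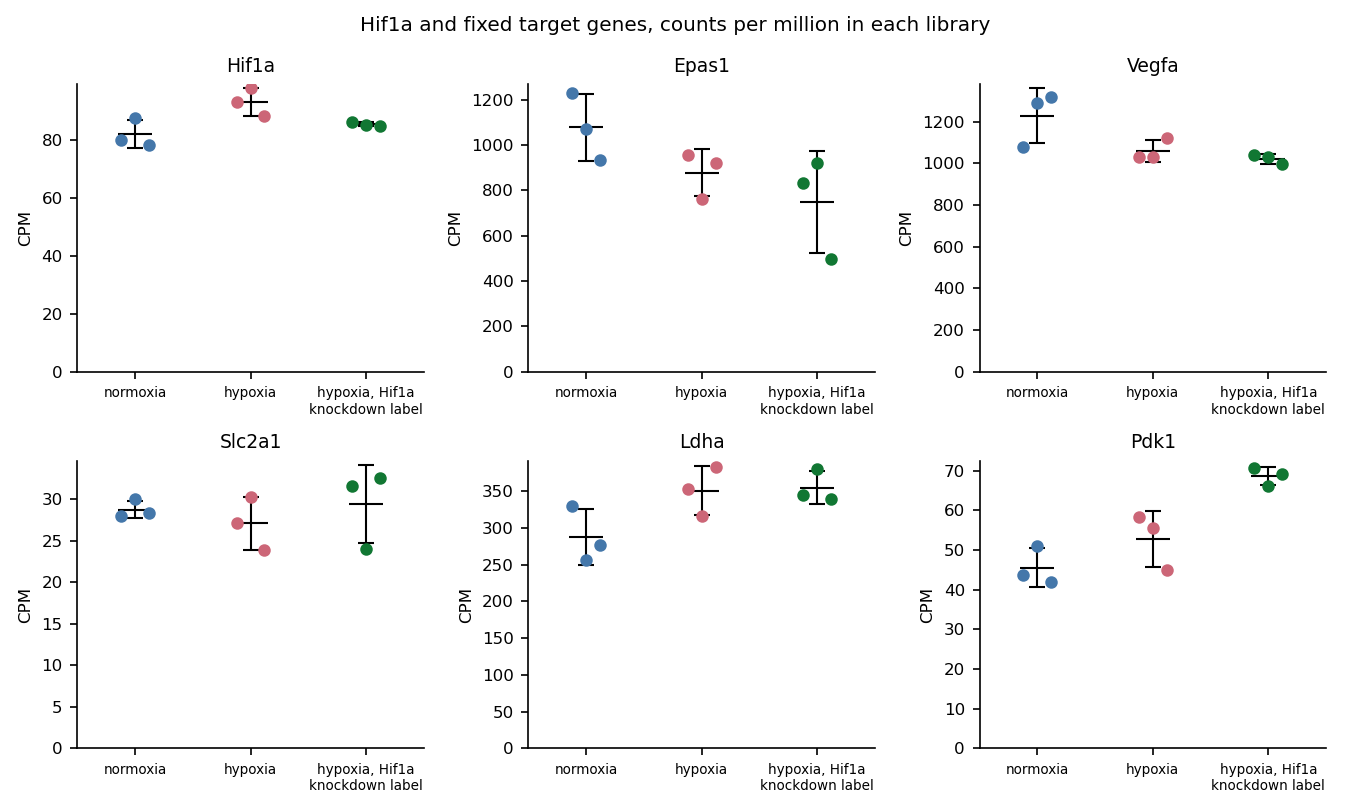
CPM (vertical axes, from 0) of 6 genes in each library, by group; points are libraries, the dash is the group mean and the whisker 1 SD (n = 3). Hif1a lies between 78.6 and 98.3 CPM in all 9 libraries.

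In hypoxia against normoxia, 26 of 31 T and NK cell genes and 19 of 28 cell cycle genes rose, 9 of 19 erythroid and 7 of 20 immediate early genes fell, and clock genes moved in both directions. As lists these were lost at adjusted p = 0.092, adjusted p = 0.17, adjusted p = 0.092, adjusted p = 0.095 and, for the clock, adjusted p = 0.095 with an estimated correlation. The granzyme gene Gzma went from 17.1 ± 1.6 to 189 ± 100 CPM (log2 fold change 3.47, SE 0.40, adjusted p = 0.0024), and Cd8a from 4.99 ± 1.4 to 63.7 ± 36 CPM (3.67, SE 0.49, adjusted p = 0.0036). Dbp, a clock output factor, went from 3.74 ± 0.68 to 138 ± 8.4 CPM (5.20, SE 0.27, adjusted p = 1.8e-05). Arntl, which encodes the clock activator BMAL1, went from 47.0 ± 5.6 to 5.87 ± 2.8 CPM (-3.00, SE 0.27, adjusted p = 0.00066). The erythroid haem enzyme gene Alas2 went from 111 ± 48 to 27.0 ± 1.9 CPM (-2.04, SE 0.28, adjusted p = 0.0045).

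In this comparison 742 genes changed, 487 of them higher and 255 lower in hypoxia, and 3068 genes had an unadjusted p under 0.05. The further largest rises were those of Gzmk (5.65, set by normoxia counts of 6, 7 and 0), Gzmb (4.40), the NK and T cell receptor gene Klrg1 (4.07), Cd8b1 (3.99), the chemokine gene Ccl5 (3.68) and the clock repressor Nr1d1 (3.63). The further largest falls were those of the clock factor Npas2 (-3.97), the neutrophil chemokine gene Cxcl5 (-3.88, set by hypoxia counts of 3, 3 and 1), Spon2 (-3.30), the heat shock gene Hspa1a (-3.21), the histone gene H4c17 (-2.62) and the red cell genes Slc4a1 and Hbb-bt (both -2.37). Of the 66 named genes past the threshold, 34 stayed past it in each of the 9 fits that left out 1 library. With limma-voom, 14 lost their call, among them Gzmk, Gzmb and Klrg1.

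Among T and NK cell genes, 26 of 31 tested members rose and none fell, with a median log2 fold change of 2.09 (29 higher when adjusted over the list alone). Nkg7 (3.57, adjusted p = 0.0021), Klrk1 (1.92, adjusted p = 0.0026) and Ccl5 (12.8-fold) are examples. Cell cycle genes went the same way, 19 of 28 higher with a median of 1.55 (27 when adjusted over the list alone), including Mcm5 (1.56), Bub1b (1.53) and Ccna2 (2.00). Both lists passed camera and lost the call with an estimated correlation (adjusted p = 0.092 and adjusted p = 0.17 with an estimated correlation). Hypoxia replicate 2 had a mean of 3.71 log2 CPM over the T and NK list against 5.06 and 4.74 in the other hypoxia libraries, and 3.09 over the cell cycle list against 4.52 and 4.38. Of the 26 B and plasma cell genes, 3 rose (5 when adjusted over the list alone): Ighg2c (5.63, set by normoxia counts of 14, 2 and 4), Igha (2.32) and Vpreb3 (0.63), with adjusted p = 0.53 with an estimated correlation. In the list of thyroid, oesophagus and thymus genes, the 2 risen members, Cd8b1 and Themis (3.28), are T cell genes (2 of 11, the same number when adjusted over the list alone, adjusted p = 0.18 with an estimated correlation).

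Of 30 interferon-stimulated genes, 9 rose (13 when adjusted over the list alone) with a median of 0.33, among them Cxcl10 (2.34), Zbp1 (1.40), Oas1a (0.82) and Ifit3 (0.80), and the call was lost at adjusted p = 0.38 with an estimated correlation. MHC class II genes rose in 7 of 10 cases by either adjustment, adjusted over the list alone or over all genes, with Ciita, their transcriptional activator (0.79), and Cd74 (0.77) as examples and adjusted p = 0.17 with an estimated correlation. Of 23 genes of monocytes and interstitial macrophages, 5 rose (12 when adjusted over the list alone), including Ly6c2 (2.14), Cx3cr1 (1.60) and C1qb (0.75), with adjusted p = 0.092 with an estimated correlation. T and NK cell genes, with their median of 2.09, moved with these 3 lists in the same libraries. Of 19 inflammatory cytokine and chemokine genes, Tnf (2.15, SE 0.36, adjusted p = 0.0095) and Ccl7 (2.39) rose and Cxcl5 and Spp1 (-1.55) fell, which left the list short of the threshold (adjusted p = 0.50; 4 higher and 3 lower when adjusted over the list alone). Il1b (-1.26, adjusted p = 0.14), Il6 (-0.28, adjusted p = 0.83), Cxcl1 (-0.02, adjusted p = 0.99) and Ccl2 (1.71, adjusted p = 0.12) did not pass.

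Erythroid genes fell in 9 of 19 cases, with a median of -1.21 (15 lower and 1 higher when adjusted over the list alone, adjusted p = 0.092 with an estimated correlation). Globin transcripts made up 0.155% to 0.424% of counts in normoxia and 0.0661% to 0.0881% in hypoxia. The globin genes Hba-a1 (-1.82), Hba-a2 (-2.16) and Hbb-bs (-1.98) fell together. Platelet and megakaryocyte genes fell in 3 of 14 cases (11 when adjusted over the list alone), namely Ppbp (-1.73), Gp6 (-1.99) and Clec1b (-0.63), with adjusted p = 0.17 with an estimated correlation. Endothelial genes fell in 4 of 28 cases (14 when adjusted over the list alone), namely Vwf (-0.60), Cldn5 (-0.75), Lyve1 (-0.76) and Calcrl (-0.56), with a list median of -0.30 and adjusted p = 0.14 with an estimated correlation. Smooth muscle and pericyte genes fell in 1 of 19 cases (Actg2, -0.75; 7 when adjusted over the list alone, adjusted p = 0.095 with an estimated correlation), and alveolar type 1 genes in 1 of 17 (Scnn1g, -0.44; 3 when adjusted over the list alone, adjusted p = 0.37 with an estimated correlation). Without hypoxia replicate 1 the alveolar type 1 list had an adjusted p of 0.057.

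Immediate early genes fell in 7 of 20 cases with a median of -0.86 (10 when adjusted over the list alone), including Dusp1 (-1.83), Atf3 (-1.13), Fosl2 (-0.80) and Jun (-0.58), with adjusted p = 0.095 with an estimated correlation. Of 17 heat shock genes only Hspa1a passed (5 lower when adjusted over the list alone, adjusted p = 0.47 with an estimated correlation). Their normoxia scores were uneven, at 7.88, 6.53 and 7.80 log2 CPM against 6.40 to 6.83 in hypoxia. Glucocorticoid-responsive genes had 3 lower members, Dusp1, Cdkn1a (-2.18) and Sgk1 (-0.73), and 1 higher, Lcn2 (0.59), with 4 lower and 1 higher when adjusted over the list alone and adjusted p = 0.61 with an estimated correlation. Without normoxia replicate 1 that list had an adjusted p of 0.23. In the unfolded protein response list Atf3 and Atf4 (-0.49) fell (2 of 21 by either adjustment, adjusted over the list alone or over all genes, adjusted p = 0.77 with an estimated correlation). The call of this list was lost without normoxia replicate 1 (adjusted p = 0.54), without normoxia replicate 3, hypoxia replicate 1 or hypoxia replicate 2 (0.18 each), without knockdown replicates 2 (0.053) or 3 (0.056), and at a filter of 1 CPM (0.051).

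Clock genes changed in 11 of 17 cases. Per3 (2.12, adjusted p = 6.1e-05), Dbp and Nr1d1 were among 7 that rose, and Clock (-0.98, adjusted p = 0.00012), Nfil3 (-2.18), Arntl and Npas2 were the 4 that fell (9 higher and 5 lower when adjusted over the list alone, adjusted p = 0.095 with an estimated correlation). Clock stood at 139 ± 3.2 CPM in normoxia, 70.3 ± 0.88 in hypoxia and 62.3 ± 3.1 in the knockdown group. The collection times of the groups are not given in the sources used here.

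**Figure D2:**
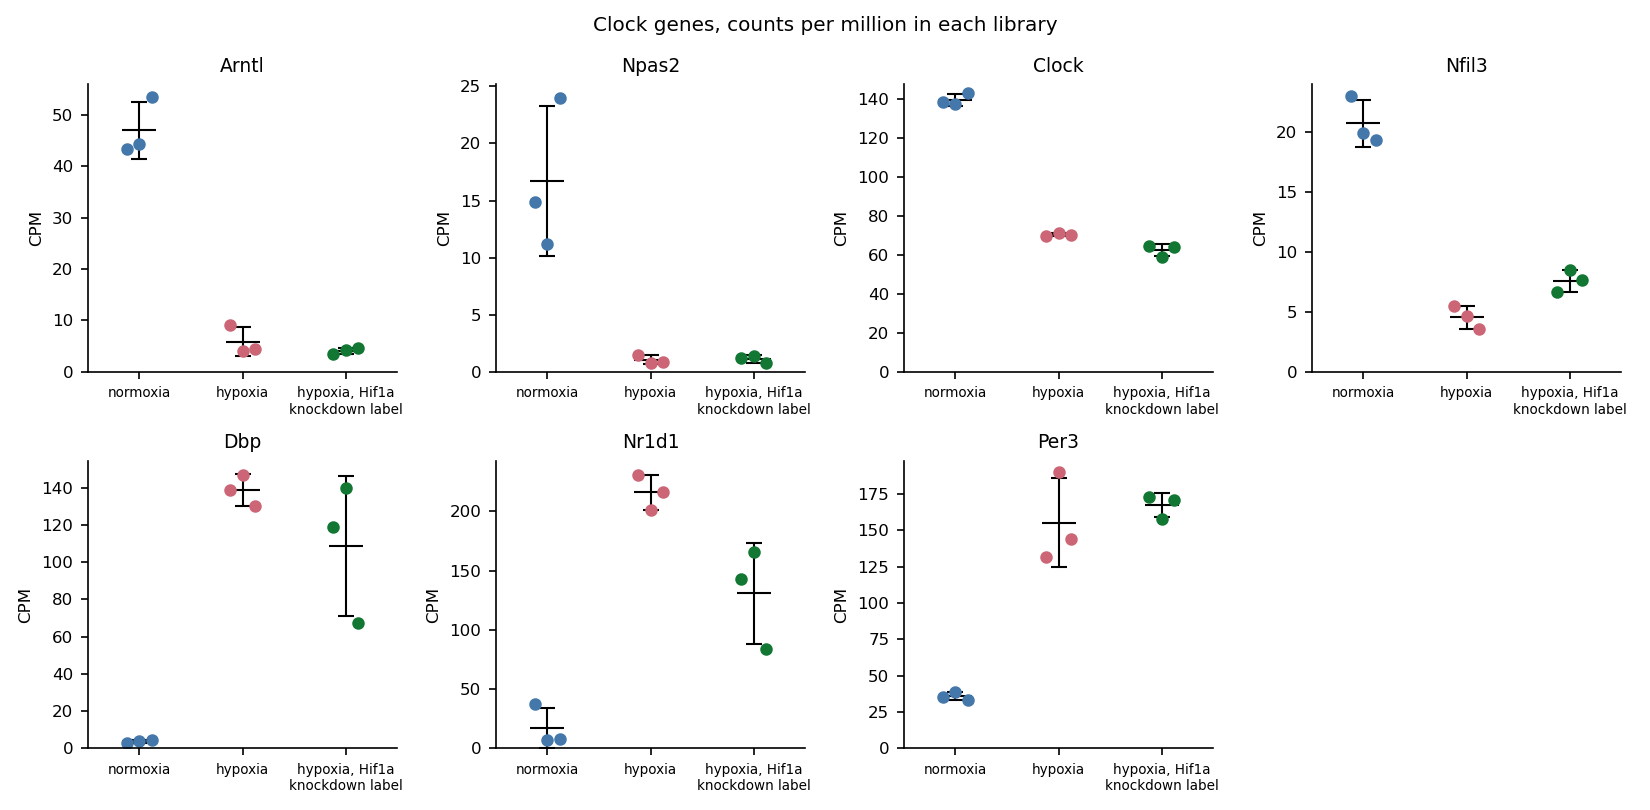
CPM (vertical axes, from 0) of 7 clock genes in each library, by group; points are libraries, the dash is the group mean and the whisker 1 SD (n = 3). Arntl, Npas2, Clock and Nfil3 are higher in each normoxia library than in any other, and Dbp, Nr1d1 and Per3 lower.

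The HIF target list did not move as a group in hypoxia. Of 35 genes, 2 were higher, 1 was lower and the median was -0.02 (3 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.91). The higher genes were the glycolytic activator Pfkfb3 (0.90) and Bhlhe40 (1.06), and the lower one was Adm (-1.67), the adrenomedullin gene. Vegfa (-0.22, SE 0.09, adjusted p = 0.25), Slc2a1 (-0.09, SE 0.13, adjusted p = 0.81), Ldha (0.29, SE 0.11, adjusted p = 0.19) and Pdk1 (0.22, SE 0.11, adjusted p = 0.36) did not pass. The glycolysis and lactate transport list passed at a median of 0.22, with 20 of 24 members above 0 and Gpi1 (0.31) and Pfkfb3 called by either adjustment, adjusted over the list alone or over all genes (adjusted p = 0.095 with an estimated correlation). None of 13 lactylation writers and erasers passed by either adjustment (adjusted p = 0.64), and Ep300 was at 120 ± 8.8 CPM in normoxia and 122 ± 12 in hypoxia. Cytosolic ribosomal protein genes passed as a list with 33 of 34 above 0, a median of 0.23 and none called by either adjustment; Rplp0 (0.35) and Rpl3 (0.32) are examples (adjusted p = 0.64 with an estimated correlation). In all, 19 of 44 lists passed, 10 towards higher and 9 towards lower levels. None passed with an estimated correlation, and 10 passed with fry, 9 of them among the 19.

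Of the lists that did not pass, nuclear oxidative phosphorylation (41 genes, adjusted p = 0.28), NRF2 antioxidant genes (22, 0.91), NF-kB feedback and endothelial adhesion (20, 0.77), p53 targets (20, 0.28), and cholesterol and fatty acid synthesis (26, 0.93) had medians between -0.05 and 0.04. The median and mean of the NF-kB list (0.04 and -0.03) and of the cholesterol list (-0.03 and 0.02) differed in sign, and camera gave both a downward direction. Alveolar type 2, club and secretory, ciliated and mesothelial cell lists had no changed member. Neither had the alveolar macrophage, adipocyte, skeletal muscle and cardiac muscle lists. The lists of neutrophils (1 higher), acute phase and mucosal defence (1 higher), neurons and glia (1 higher), dendritic and mast cells (2 higher, 1 lower), fibroblasts (2 lower), extracellular matrix (4 lower), fatty acid oxidation (3 lower) and mitochondrially encoded genes (1 lower) had few. Some of these lists passed camera when 1 library was left out: oxidative phosphorylation (adjusted p = 6.0e-04), neutrophils (0.00088) and adipocytes (0.00052) without normoxia replicate 1, and neutrophils (0.020) and mesothelium (0.0034) without hypoxia replicate 1. Matrix (0.00049), acute phase (0.0057), club (0.014) and adipocyte (0.011) lists passed without hypoxia replicate 3, and fatty acid oxidation without normoxia replicate 3 (0.0051). Alveolar macrophages passed in several such fits (0.0039 without knockdown replicate 1 as the lowest). The number of genes higher in hypoxia was 138 without normoxia replicate 3, 201 without hypoxia replicate 1, 206 without hypoxia replicate 3 and 750 without hypoxia replicate 2, and was 285 and 301 without normoxia replicates 1 and 2. The number lower was 71, 91 and 95 without normoxia replicate 3, hypoxia replicate 1 and hypoxia replicate 3.

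Between the libraries labelled knockdown and the hypoxia libraries, 28 of 30 interferon-stimulated genes rose, while 12 of 31 T and NK cell genes and 3 of 26 B and plasma cell genes fell. The interferon list held at adjusted p = 0.0024 with an estimated correlation, and the other two did not (adjusted p = 0.30 and adjusted p = 0.46 with an estimated correlation). Irf7, a master regulator of type I interferon responses, went from 33.1 ± 7.6 to 373 ± 57 CPM (log2 fold change 3.49, SE 0.18, adjusted p = 4.4e-06). Ifit3, an antiviral effector gene, went from 74.3 ± 6 to 418 ± 41 CPM (2.49, SE 0.13, adjusted p = 4.9e-06). Cd8a went back from 63.7 ± 36 to 6.74 ± 3.1 CPM (-3.25, SE 0.47, adjusted p = 0.0038), and Trac, the constant segment of the T cell receptor alpha chain, from 22 ± 8.9 to 3.65 ± 1.1 CPM (-2.58, SE 0.34, adjusted p = 0.002). Since Hif1a itself differed by -0.13, these are differences between labels, not shown to follow a lower Hif1a transcript.

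In this comparison 301 genes changed, 222 higher and 79 lower, and 1928 had an unadjusted p under 0.05. The largest further rises were those of Gbp10 (4.47), Slfn4 (3.84), the macrophage gene Cd5l (3.82), Acod1 (3.08), which encodes the enzyme that makes itaconate, Isg15 (3.03), Gbp6 (2.88) and Zbp1 (2.86). The largest further falls were those of Gzmk (-4.33), Cd8b1 (-3.63), Themis (-3.09), the chemokine receptor gene Cxcr3 (-2.66), Icos (-2.62), Cd3e (-2.58) and Cd5 (-2.50). Of the 37 named genes past the threshold, 26 stayed past it in each fit without 1 library, and 6, among them Gzmk and Cd8a, lost their call with limma-voom.

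Interferon-stimulated genes rose in 28 of 30 cases (29 when adjusted over the list alone) with a median of 2.30, Oasl2 (2.58), Usp18 (2.11) and Isg15 among them. This list held with an estimated correlation (adjusted p = 0.0024), the 1 list of this comparison to do so. Beside it, 5 of 24 neutrophil genes rose (12 when adjusted over the list alone; median 0.96, adjusted p = 0.15 with an estimated correlation), including Ly6g (2.63), Il1r2 (2.23) and S100a8 (1.68), as did 3 of 23 genes of monocytes and interstitial macrophages (9 when adjusted over the list alone, adjusted p = 0.064 with an estimated correlation), Fcgr4 (1.87), C1qa (0.87) and C1qb (0.70). MHC class II genes rose in 2 of 10 cases by either adjustment, adjusted over the list alone or over all genes (Ciita, 1.50, and H2-DMb1, 0.52, adjusted p = 0.64 with an estimated correlation). Acute phase genes rose in 2 of 16 (S100a8 and S100a9, 1.67; 4 when adjusted over the list alone, adjusted p = 0.19 with an estimated correlation). Of 22 NRF2 antioxidant genes Osgin1 (0.55) rose (4 when adjusted over the list alone, adjusted p = 0.59 with an estimated correlation). No alveolar macrophage gene was called by either adjustment, adjusted over the list alone or over all genes, although the list passed with 17 of 19 above 0, Marco (0.71) and Mrc1 (0.47) among them (adjusted p = 0.82 with an estimated correlation). Without knockdown replicate 2 the adjusted p was 0.25 for that list, 0.058 for MHC class II and 0.065 for NRF2 genes, and without hypoxia replicate 3 it was 0.10 for NRF2 genes.

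T and NK cell genes fell in 12 of 31 cases with a median of -1.06 (20 lower and 1 higher when adjusted over the list alone, adjusted p = 0.30 with an estimated correlation). B and plasma cell genes fell in 3 of 26 (6 when adjusted over the list alone, adjusted p = 0.46 with an estimated correlation), namely Ighg2c (-6.65, set by knockdown counts of 7, 3 and 0), Igha (-3.48) and Igkc (-1.61). The mean level of Ighg2c was 0.415 ± 0.41 CPM in normoxia, 20.7 ± 11 in hypoxia and 0.196 ± 0.2 in the knockdown group. Cd8b1 and Themis were also the 2 lower genes of the thyroid, oesophagus and thymus list (3 of 11 when adjusted over the list alone, adjusted p = 0.30 with an estimated correlation). Cell cycle genes passed as a list with all 28 below 0 and a median of -0.74, yet no member was called by either adjustment, adjusted over the list alone or over all genes; Ccnb1 (-1.43, adjusted p = 0.23) and Tyms (-0.85, adjusted p = 0.13) had values of this kind (adjusted p = 0.64 with an estimated correlation). Heat shock genes likewise passed with none called and a median of -0.30 (Hsph1, -0.88, adjusted p = 0.50, list adjusted p = 0.96 with an estimated correlation). Without hypoxia replicate 2 the list had an adjusted p of 0.068.

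Erythroid genes fell again, in 6 of 19 cases with a median of -1.0 (8 when adjusted over the list alone, adjusted p = 0.15 with an estimated correlation), including Hba-a1 (-1.98), Hba-a2 (-1.88) and Hbb-bs (-1.62). Globin transcripts made up 0.0169% to 0.0279% of counts. Platelet genes, by contrast, had no called member and a median of 0.08. The clock list did not pass (none of 17 called over all genes, 1 higher when adjusted over the list alone, median 0.00, camera adjusted p = 0.98). The HIF target list (35 genes; Pfkfb3 higher, 0.44; adjusted p = 0.45), glycolysis (24 genes, 2 higher, adjusted p = 0.22) and the inflammatory cytokine list (19 genes, none called, adjusted p = 0.45) did not pass. Nor did the lactylation list (13 genes, none called, adjusted p = 0.98). Tnf (-0.17, adjusted p = 0.93), Il1b (1.54, adjusted p = 0.14), Il6 (-0.11, adjusted p = 0.97), Cxcl1 (0.50, adjusted p = 0.82), Ccl2 (0.27, adjusted p = 0.92), Vegfa (-0.05, adjusted p = 0.92) and Ldha (0.02, adjusted p = 0.98) did not pass either. Slc2a1 (0.12, adjusted p = 0.84) and Pdk1 (0.38, adjusted p = 0.17) also fell short, although the 95% interval of Pdk1, 0.13 to 0.62, lay above 0. Of the 24 glycolysis genes, 4 were higher when adjusted over the list alone. In all, 13 lists passed, 7 towards higher and 6 towards lower levels, 1 with an estimated correlation and 5 with fry. Lists short of the threshold that passed without 1 library include adipocytes (adjusted p = 0.0011 without knockdown replicate 2), matrix (0.0046 without hypoxia replicate 1) and alveolar type 2 cells (0.0081 without knockdown replicate 3). The number of lower genes was 243 without hypoxia replicate 2, 37 and 39 without hypoxia replicates 1 and 3, and 30, 46 and 30 without knockdown replicates 1, 2 and 3.

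**Figure D3:**
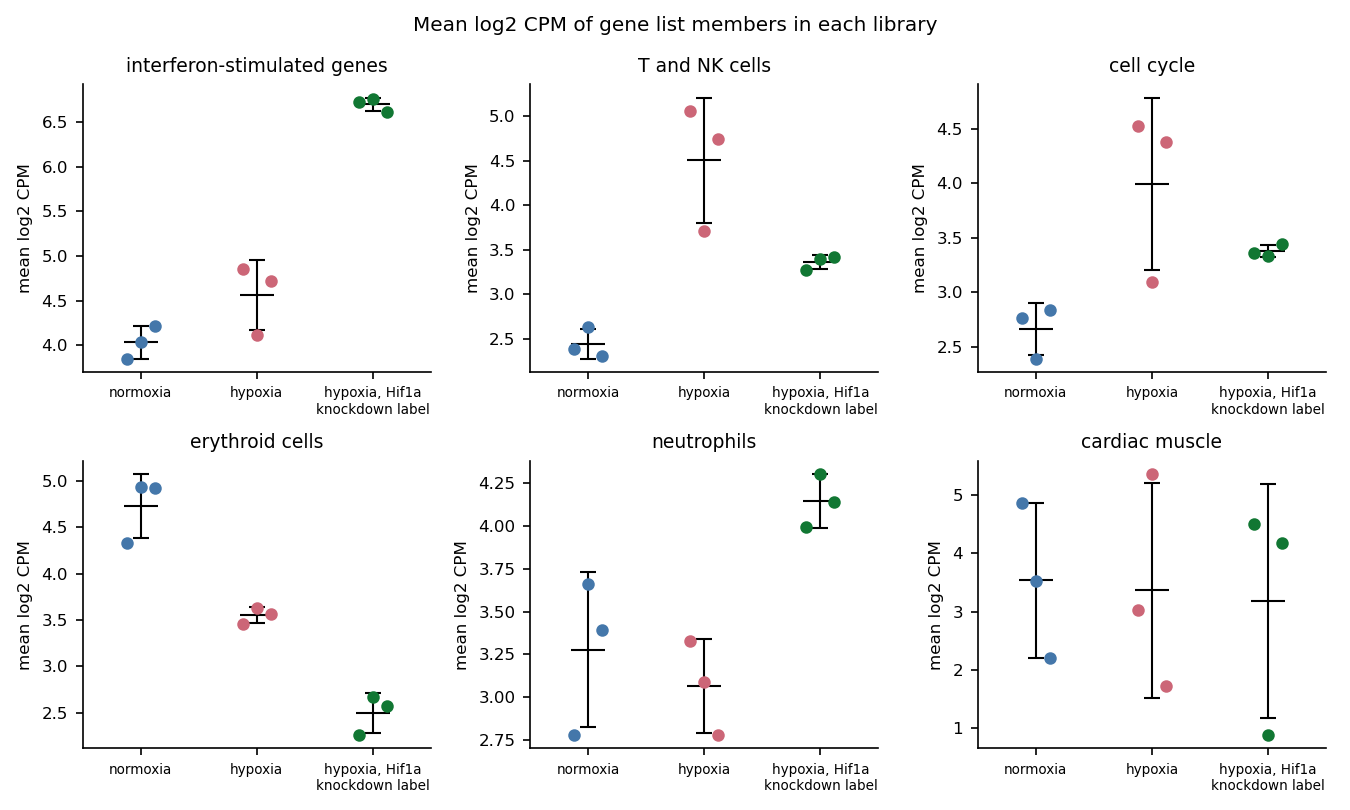
Mean log2 CPM over the members of 6 gene lists (vertical axes, not from 0) in each library, by group; points are libraries, the dash is the group mean and the whisker 1 SD (n = 3). Interferon-stimulated genes are highest in the 3 knockdown libraries (6.61 to 6.76), T and NK genes in the hypoxia libraries (3.71 to 5.06), and cardiac muscle genes spread widely inside each group.

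In the knockdown group against normoxia, interferon-stimulated genes were higher in 29 of 30 cases with a median of 2.80 (30 when adjusted over the list alone), and Gbp10 went from 0.61 ± 0.15 to 36.0 ± 0.95 CPM (log2 fold change 5.86, SE 0.32, adjusted p = 1.8e-06). Erythroid genes were lower in 14 of 19 cases with a median of -2.38 (14 lower and 1 higher by either adjustment, adjusted over the list alone or over all genes), and Hba-a1 went from 657 ± 260 to 47.1 ± 15 CPM (-3.80, SE 0.30, adjusted p = 2.1e-05). Monocyte and interstitial macrophage genes were higher in 12 of 23 (18 when adjusted over the list alone; median 1.10), among them Fcgr4 (2.85), Ly6c2 (2.76) and C1qb (1.45). These 3 lists held with an estimated correlation (adjusted p = 0.0087, adjusted p = 0.038 and adjusted p = 0.0087).

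A total of 1446 genes changed, 842 higher and 604 lower, with 4058 at an unadjusted p under 0.05. Further large rises were those of Cd5l (5.28), Dbp (4.85), the interferon-inducible GTPase genes Tgtp1 (4.58) and Iigp1 (4.15), Zbp1 (4.27), Oas1g (4.18) and Irf7 (4.04). Further large falls were those of Slc4a1 (-4.92), Spon2 (-4.49), Hspa1a (-4.48), Hbb-bt (-4.46) and Hspa1b (-4.33). Trim10 went from 4.08 ± 2.3 to 0.0958 ± 0.089 CPM, with counts of 2, 0 and 3, so its fold is set by a few counts. Tyrp1, a melanocyte gene (-4.78), rested on 17.1 CPM in normoxia replicate 1 against 1.93 and 1.50 in the other normoxia libraries. Of the 80 named genes past the threshold, 54 stayed past it in each fit without 1 library.

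MHC class II genes were higher in 7 of 10 by either adjustment, adjusted over the list alone or over all genes (Ciita, 2.29; H2-DMa, 1.12, adjusted p = 0.14 with an estimated correlation), and T and NK genes in 11 of 31 (12 when adjusted over the list alone; Ncr1, 2.75; Prf1, 2.37, adjusted p = 0.50 with an estimated correlation). Of 28 cell cycle genes Bub1b (1.03) was higher (5 when adjusted over the list alone, adjusted p = 0.69 with an estimated correlation). Neutrophil genes were higher in 7 of 24 (14 when adjusted over the list alone; Slfn4, 3.30; Fpr2, 1.31, adjusted p = 0.35 with an estimated correlation). So were acute phase genes in 7 of 16 (10 when adjusted over the list alone; Retnlg, 1.79; Lrg1, 0.84, adjusted p = 0.13 with an estimated correlation) and alveolar macrophage genes in 3 of 19 (11 when adjusted over the list alone; Chil3, 1.14; Mrc1, 0.80, adjusted p = 0.54 with an estimated correlation). Glycolysis genes were higher in 5 of 24 (12 higher and 1 lower when adjusted over the list alone; Pfkfb3, 1.34; Hk3, 1.23; Pdk1, 0.59, adjusted p = 0.093 with an estimated correlation). The 11 clock genes called in hypoxia were called in the same direction here, within 8 higher and 4 lower by either adjustment, adjusted over the list alone or over all genes (Per3, 2.22; Clock, -1.16; Arntl, -3.52, adjusted p = 0.16 with an estimated correlation).

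Heat shock genes were lower in 10 of 17 (15 when adjusted over the list alone; Hsph1, -2.04; Dnajb1, -1.41, adjusted p = 0.39 with an estimated correlation), and immediate early genes in 8 of 20 (9 when adjusted over the list alone; Nr4a3, -2.30; Klf4, -1.26, adjusted p = 0.23 with an estimated correlation). Endothelial genes were lower in 8 of 28 (13 when adjusted over the list alone; Cldn5, -0.81; Plvap, -0.80; Cdh5, -0.56, adjusted p = 0.21 with an estimated correlation), platelet genes in 4 of 14 (10 when adjusted over the list alone; Ppbp, -1.60; Itgb3, -0.77, adjusted p = 0.35 with an estimated correlation), and smooth muscle genes in 4 of 19 (6 when adjusted over the list alone; Synpo2, -0.70; Acta2, -0.64, adjusted p = 0.21 with an estimated correlation). Extracellular matrix genes were lower in 5 of 29 and higher in 1 (7 lower and 1 higher when adjusted over the list alone; Thbs1, -1.22; Col5a1, -0.95; Tgfbi, 0.86, adjusted p = 0.69 with an estimated correlation). Alveolar type 1 genes were lower in 3 of 17 (6 when adjusted over the list alone; Akap5, -0.57, adjusted p = 0.61 with an estimated correlation). The ribosomal protein list (Rpl3, 0.36; median 0.19; none when adjusted over the list alone) and the adipocyte list (none called by either adjustment; median 1.09; Fabp4, 1.49, adjusted p = 0.25) passed with adjusted p = 0.85 and adjusted p = 0.72 with an estimated correlation. In all, 20 lists passed, 12 towards higher and 8 towards lower levels, 3 of them also with an estimated correlation. With fry 12 lists passed, 11 of them among the 20. The further one was the inflammatory cytokine list (fry adjusted p = 0.034, camera adjusted p = 0.22). Of its 19 genes 5 were higher and 2 lower (6 and 2 when adjusted over the list alone). Tnf stood above normoxia (1.98, edgeR adjusted p = 0.0074). The HIF target list did not pass (camera adjusted p = 0.59), with 4 of 35 genes higher and 2 lower (6 and 5 when adjusted over the list alone). Among the other lists, glucocorticoid-responsive genes (adjusted p = 0.00095 without knockdown replicate 3) and oxidative phosphorylation (0.0057 without normoxia replicate 1) passed when a library was left out. Of the 20 lists, 16 stayed without normoxia replicate 3, where the matrix (adjusted p = 0.059), ribosomal (0.057), alveolar type 1 (0.087) and adipocyte (0.13) lists were lost. Without knockdown replicate 3, 17 stayed, with the matrix (0.092), alveolar type 1 (0.058) and adipocyte (0.092) lists lost. Without normoxia replicate 2 the ribosomal (0.090) and adipocyte (0.096) lists were lost, without knockdown replicate 1 the alveolar type 1 (0.068) and adipocyte (0.20) lists, without knockdown replicate 2 the ribosomal list (0.13) and without hypoxia replicate 2 the alveolar type 1 list (0.056). Without normoxia replicate 3, 457 genes were higher and 258 lower; without knockdown replicate 2 these were 529 and 352, and without knockdown replicates 1 and 3 the lower genes were 338 and 375.

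Genes that changed in hypoxia and again with the knockdown label fell into distinct directions. Of 90 genes called in both comparisons, 52 were higher in hypoxia and lower in the knockdown group, none went down and then up, 33 were higher in both and 5 lower in both. The 52 include the T cell genes Cd3d (2.08, then -2.20), Cd28 (2.42, then -2.35), Lat (2.05, then -2.08) and Themis (3.28, then -3.09) together with immunoglobulin segments. The 33 include the interferon-inducible genes Igtp (0.93, then 2.78), Mx1 (1.35, then 1.93) and Tap1 (1.18, then 1.45), and the 5 are Hba-a1, Hba-a2, Hbb-bs, Alas2 and Adamts1 (-0.87, then -0.77). These examples were chosen after their values were seen. Independent lists of these sizes would share 2.19, 3.22, 6.15 and 1.15 genes in the 4 combinations, in the order up then down, down then up, up in both and down in both. In 20 simulations without any change both overlaps were 0, but with no gene changed few calls can arise. The hypoxia libraries were therefore also split into 1 and 2, so that the comparisons shared none. This test was added after the results had been seen, and 1 side always rests on a single library. The 6 such splits gave 13 to 41 genes up and then down (0.143 to 1.07 for independent lists), none down and then up, and 4 to 67 in the same direction (0.628 to 6.58). Both excesses remained in these splits, although the spread used for the single library came from the other libraries. The hypoxia libraries enter the comparisons with opposite signs, so sharing them can add only to genes moved in opposite directions. Part of the 52 may therefore still come from the sharing, which works against an overlap in the same direction.

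Across the tested genes, which are not independent replicates, the log2 fold changes of the comparisons correlated at -0.302, against -0.492 in the simulations, and their covariance was -0.0706 against -0.0476. The difference of covariances was -0.0229. With the hypoxia libraries split, the correlation was between -0.136 and 0.132, so an opposite movement across genes in general was not seen. Hypoxia against normoxia and knockdown against normoxia, which share the normoxia libraries, correlated at 0.669 (0.504 in the simulations) with a covariance of 0.201 (0.0491). Of the 742 genes changed in hypoxia, the knockdown mean lay between the normoxia and hypoxia means in 458 (61.7%), beyond the hypoxia mean in 257 (34.6%) and past the normoxia mean in 27. Of the 742 genes, 452 (60.9%) were also called in the same direction in knockdown against normoxia. These comparisons share the normoxia libraries, and the genes were selected for a large difference between hypoxia and normoxia. Such a selection by itself draws the mean of another group back from the hypoxia mean. Part of both shares comes from the shared libraries and the selection, and the size of that part was not tested. The shares are therefore no measure of a reversal with the knockdown label. The 38 genes moved the same way were 15 without hypoxia replicate 3, 17 without normoxia replicate 3 and 18 without hypoxia replicate 1. The count of 52 was 203 without hypoxia replicate 2, 24 and 27 without hypoxia replicates 1 and 3, 25, 31 and 23 without knockdown replicates 1, 2 and 3, and 21 without normoxia replicate 3.

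**Figure D4:**
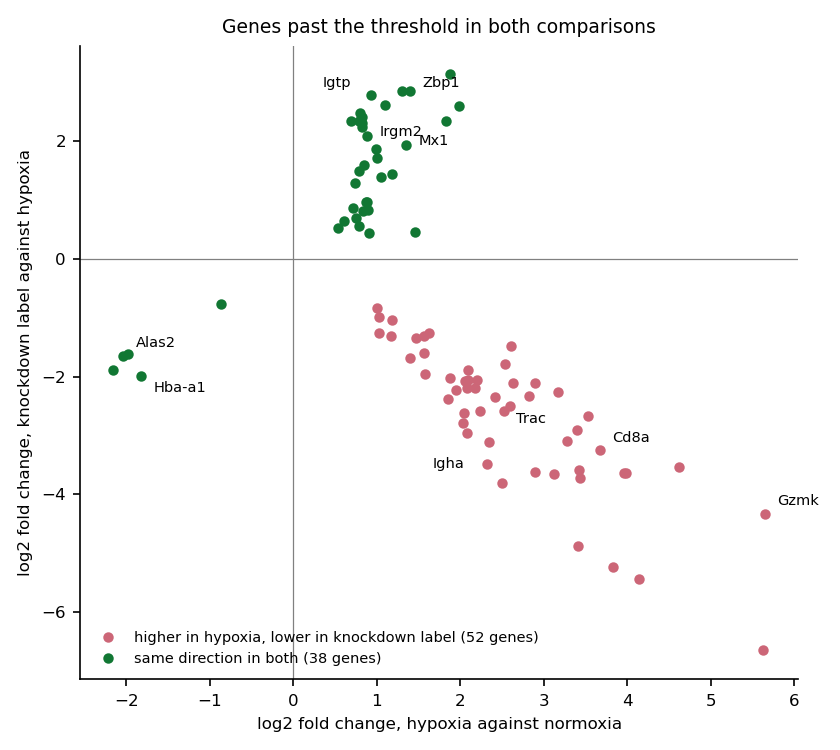
Log2 fold changes of the 90 genes past the threshold in both comparisons, hypoxia against normoxia on the horizontal axis and knockdown label against hypoxia on the vertical axis; each point is a gene. The 52 genes at lower right rose in hypoxia and were lower in the knockdown group, and the 38 others kept their direction.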

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

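The cardiac muscle covariate was chosen after seeing the data; it gave 640 genes higher and 380 lower in hypoxia against normoxia, and 63 genes moved the same way in both comparisons against 38. That count was 93 with DESeq2, 107 without a filter and 22 in the 6 libraries. DESeq2 size factors within edgeR and the filter of at least 1 CPM in 3 libraries kept every count within 1.5 times. Genes higher in hypoxia numbered 814 with the DESeq2 Wald test, 851 without a filter, 267 with limma-voom and 276 in the 6 libraries; genes lower numbered 495, 442 without a filter, 168 in the 6 libraries and 64 at an absolute log2 fold change of at least 1. Genes higher with the knockdown label against hypoxia numbered 362 with DESeq2, 376 without a filter and 143 at the fold limit; genes lower numbered 205, 268 without a filter and 40 with limma-voom. Against normoxia, 445 higher and 137 lower passed the fold limit, and DESeq2 gave 927 lower. Genes differing among the groups were 2258 with DESeq2 and 2195 without a filter. Genes moved in opposite directions were 119 with DESeq2, 179 without a filter, 18 with limma-voom and 30 in the 6 libraries. The fold limit keeps fewer genes by construction; for the other settings the cause was not tested. Lists past the threshold were 0, 1 and 3 with an estimated correlation, and 10, 5 and 12 with fry.

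Leaving out 1 library gave 138 to 750 genes higher and 71 to 248 lower in hypoxia against normoxia, 159 to 242 and 30 to 243 with the label against hypoxia, 457 to 935 and 258 to 632 against normoxia, 678 to 1647 among the groups and 21 to 203 in opposite directions. Lists past the threshold were 19 to 25, 13 to 17 and 18 to 21. Fewer samples lower the power; for the rise without hypoxia replicate 2, which had the lowest T and NK score of its group, the cause was not tested. The cardiac muscle list turned its direction without hypoxia replicate 2 (adjusted p = 0.0084 in hypoxia against normoxia and 0.017 with the label against hypoxia), and the cholesterol list without hypoxia replicate 3 (adjusted p = 0.047); the cause was not tested. Over all libraries left out, the adjusted p of the cardiac muscle list reached 0.98 in hypoxia against normoxia and 0.70 with the label, and that of the cholesterol list ran from 0.028 (without hypoxia replicate 1) to 0.94.

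The data gave no sign that the replicate numbers pair the samples, although the labels do not say and a pairing was not excluded. Deviations from the group means correlated at -0.423 to 0.274 between same-numbered libraries of different groups, with 2 of 9 pairs above 0.1. Between libraries with other numbers they correlated at -0.305 to 0.439. With the replicate block, genes higher and lower in hypoxia were 282 and 118, lower genes 39 with the label against hypoxia and 352 against normoxia, genes differing among the groups 838 and genes moved in opposite directions 27. Depth limits the genes near the floor of 0.166 to 0.193 CPM, such as Trim10 in the knockdown group.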

Other observations

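All tests in this part were chosen after the results had been seen, as were the gene sets of T lineage, NK and cytotoxic, follicle, clock phase and class I genes; the other lists were written down before the data were examined. T lineage genes and a set of 9 NK and cytotoxic genes differed in their behaviour in the libraries labelled knockdown. All 13 T lineage genes, such as Cd3e, Cd4 and Trac, rose in hypoxia (median log2 fold change 2.23), 11 of 13 fell with the label against hypoxia (median -2.35, 95% interval -2.58 to -2.05), and against normoxia none was called (median 0.07). All 9 genes of the NK and cytotoxic set, such as Ncr1, Klrb1c and Prf1, rose in hypoxia (median 1.97), none was called with the label against hypoxia (median -0.10, interval -0.56 to 0.28), and all 9 were higher than in normoxia (median 2.18). Ncr1 stood at 3.74, 14.3 and 25.2 CPM in normoxia, hypoxia and knockdown, and Cd3e at 3.66, 17.3 and 2.90. By edgeR, 0 of the 9 passed in knockdown against hypoxia; the largest change was that of Ncr1 (0.81, adjusted p = 0.24). This depends on the genes chosen: Gzmk, a granzyme gene outside the set, fell with the label against hypoxia (-4.33, adjusted p = 0.0025). Nkg7 (-1.06, adjusted p = 0.23), Ccl5 (-1.24, adjusted p = 0.094) and Klrg1 (-1.60, adjusted p = 0.26), also outside it, had lower means without passing. The T lineage figures depend on the choice of genes too. Lck, Cd2, Il7r, Foxp3 and Zap70 of the T and NK list were left out of that set. Tcf7 and Lef1 were also left out and passed in no comparison. Lck rose and fell (2.61, then -1.47). Over the whole T and NK list, 26 of 31 genes rose in hypoxia and 12 fell with the label against hypoxia. Of 12 genes of class I antigen presentation, 9 rose in hypoxia (median 0.81) and 9 with the label against hypoxia (median 0.82). These were not the same 9 genes. H2-K1, B2m and H2-D1 passed only in hypoxia, and Psmb10, Tap2 and Tapbp only with the label. Nlrc5 (1.05, then 1.39) and Psmb9 (0.88, then 0.97) were among those that passed at both steps.

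Heart, airway and fat transcripts varied together over the 9 libraries. The cardiac muscle score ran from 0.88 to 5.36 log2 CPM and correlated over the 9 libraries with the club and secretory cell score (r = 0.817, exact permutation p = 0.011, adjusted 0.014; rho = 0.80, exact permutation p = 0.014, adjusted 0.021) and with the adipocyte score (r = 0.805, exact permutation p = 0.014, adjusted 0.014; rho = 0.683, exact permutation p = 0.05, adjusted 0.05). The club and adipocyte scores correlated at r = 0.963 (exact permutation p = 0.00046, adjusted 0.0014; rho = 0.867, exact permutation p = 0.0045, adjusted 0.014). The adjustment covers only these 3 two-sided relations. They were chosen among the pairs of lists after the results had been seen, and the adjustment leaves that choice out. The p-values therefore describe these pairs as chosen and are no test of whether the relation exceeds that choice. Without the 2 libraries farthest from the median of the first score, r was 0.779, 0.816 and 0.935. Groups of 3 libraries are too few for the relation within a group, and the labels give no batch.

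Interferon-stimulated genes were higher in each knockdown library (6.61 to 6.76 log2 CPM) than in any hypoxia library (4.12 to 4.85). More T and NK cells taken as 1 group were argued against by the median of -1.06 of that list (interval over genes -1.70 to -0.64), which the T lineage genes carry (-2.35). The 9 genes of the NK and cytotoxic set argue against a rise of NK cells alone as large as that of the interferon list (median 2.30). Their median was -0.10 (interval -0.56 to 0.28) and none was called. A smaller rise of NK cells stays open, as Ncr1 had a higher mean without passing (0.81, edgeR adjusted p = 0.24). More monocytes, macrophages and neutrophils with their usual transcripts were argued against by the interferon list rising 1.67 further than the 47 pooled markers of these cells (interval 1.24 to 1.90), though a changed state of such cells stays open. A fall of Hif1a transcript by 1 log2 unit across the lung was argued against by the lower bound of its interval, -0.29; a smaller, cell-restricted or earlier loss was not tested. A response to the delivery of the knockdown reagent cannot be told apart from an effect of the target, since the labels name no hypoxic animals given a control reagent.

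Clock genes of opposite phases moved apart by 4.20 log2 units in hypoxia against normoxia (interval 2.58 to 6.38), with medians of 2.02 and -2.18. A different collection time in normoxia and a clock shift by hypoxia may each give this and cannot be told apart, because no collection times are given. Between the knockdown and hypoxia libraries the same difference was -0.11 (interval -0.82 to 0.49). The interval lies within a bound of 1, which was set after the results had been seen. This argues against a clock difference of 1 log2 unit or more between these groups, while a smaller one stays open. If collection times did differ, rhythmic genes outside the clock list could contribute to the 742 changes in hypoxia against normoxia, which was not tested.

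In hypoxia against normoxia, 26 of 31 T and NK cell genes and 19 of 28 cell cycle genes were higher. Neither list held with an estimated correlation. The 19 follicle and naive lymphocyte genes were taken as a sign of lymph node tissue in the hypoxia libraries. None of the 19 was called in hypoxia against normoxia (median log2 fold change 0.27, interval 0.15 to 0.41). Their median gain was 2.93 CPM against 18.7 CPM for the T lineage genes (difference -15.7, interval -19.3 to -10.1). Ccr7 went from 15.8 to 17.4 CPM. Both sets were chosen after the results had been seen, and each T lineage gene in its set had risen. The direction and size of this gap follow in part from that choice, so its interval is no test. The small gain of the follicle genes goes against lymph node tissue as the main source, for these genes only. Tcf7 (0.31) and Lef1 (0.72), members of the T and NK list that did not pass, were placed in the follicle set. An equal rise of all leukocytes was argued against by the T and NK list rising 2.00 further than the 43 pooled neutrophil and alveolar macrophage markers (interval 1.72 to 2.47). The lists of monocytes and interstitial macrophages (median 0.54) and of B and plasma cells (0.32) also had medians above 0, so a rise of several leukocyte types stays open. An influx of effector lymphocytes with hypoxia is a candidate explanation that was not tested. An infection or another difference between cohorts of animals stays open and was not tested either.

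Other splits of the libraries were compared with the real groups. For 3 groups, 1 of 100 drawn splits of the 280 possible, the real one with 1397 genes, reached that count (a share of 0.01). The highest other split gave 460 and kept the normoxia libraries together. Splits that mix the real groups also widen the spread within a group, which lowers their counts. The real count thus stands out among these splits, but a difference between cohorts or batches of samples is not tested by them. For the pairwise comparisons 10 splits exist, too few for a share under 0.05: the real splits gave 742, 301 and 1446 genes, reached by 1 split each, and the highest other split gave 0 in each by edgeR.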
